A study of Mus musculus with 6 samples.

How the data were processed

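Total RNA from mouse abdominal aorta was homogenised in Trizol and purified on columns, and libraries were made from RNA bound to poly-T beads with random hexamer priming, per the labels' protocols. Poly-T selection enriches polyadenylated transcripts. The deposited table holds raw whole-number read counts per gene for 54532 genes in 6 libraries, 3 KO and 3 WT. The file headers give a column for each library and do not say whether animals were pooled. HISAT2 2.0.5, featureCounts 1.5.0-p3 and the genome build GRCm38 are named in the submitters' processing notes. The strand setting, the treatment of reads that match several genes and the annotation release are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and reads of near-identical copies can be dropped or split. The labels name the aneurysm only by its induction and the day, so the method of induction is not given in the sources used here.

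Gene positions and biotypes came from GENCODE mouse release 21 on GRCm38, which gave a position for 54495 of the 54532 gene identifiers. Exon overlap was the percent of a gene's exon bases covered by exons of other genes on either strand. At least 1 count was present for 29498 genes. Library totals ranged from 17248918 to 21872027 counts. Pairs of libraries were compared by a chi-square test over genes with at least 20 counts, which gave 25.6 to 81 per degree of freedom, so no pair was a repeat of 1 library.

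Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the genotype, which left 16237, and libraries were scaled by TMM. KO was tested against WT by edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment over all tested genes and an adjusted p under 0.05 as the threshold. The standard error of a log2 fold change was its size divided by the square root of F. Printed CPM values used TMM-scaled library sizes, and log2 CPM used a prior count of 2. The median log2 fold change of all tested genes was 0.006, and 0.004, 0.019 and 0.04 under DESeq2 size factors, upper quartile factors and library size alone. The biological coefficient of variation was 19.6%.

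The lists of genes, the named-gene rule, the tests and most alternatives were fixed before the data were examined. There were 56 lists for the vessel wall, matrix, leukocytes, signalling, metabolism, RNA state and neighbouring tissues, and 50 had at least 5 members tested. Lists were tested by limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation and by fry. With the preset correlation 20 lists were called, 9 higher and 11 lower in KO. With an estimated correlation 0 were called, and fry, which tests whether a list's genes move one way, called 0. Members were also adjusted over the list alone. A list score was the mean log2 CPM of its tested members, compared by an exact permutation test, which for 3 against 3 cannot give a p under 0.1.

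Genes were named by a rule. It took Olfr2, and the 10 highest and 10 lowest fold changes among passing genes whose KO libraries all lay on one side of the WT libraries with a mean of at least 1 CPM in either group. Where fewer than 10 passed, those with the smallest unadjusted p completed the 10. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out of that part. The rule also took the 5 called genes of highest mean CPM per direction, up to 4 members of each list by smallest unadjusted p, a fixed panel of vessel wall and inflammation genes, and the sex-linked list. Not every gene that the rule takes is reported here. Genes outside the rule were chosen after their values were seen: Chil3, Hspa1a, Jchain, Lyz1, Lyz2 and Olfr1033, and those called near Olfr2 or as single calls with libraries left out.

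The edgeR test was tried on counts simulated for KO against WT, with 15993 genes tested. It recovered 7.5% of genes changed 1.5-fold, 49.2% of those changed 2-fold and 83.1% of those changed 4-fold, with 11 false calls among 103. DESeq2 made 142 calls there, of which 25 were false. For both tests the share of false calls was above the level that the threshold sets. The edgeR test made 103 calls on the simulated counts but 2 on the real ones. The recovery rates therefore describe the simulated counts and may not hold for the real libraries. Alternatives used other scalings, filters, DESeq2 1.42.0, limma-voom, other quasi-likelihood fits, a replicate block and each library left out in turn. Leaving out KO replicate 3 with WT replicate 2, the white adipocyte score as a covariate, leaving out mitochondrially encoded genes, and leaving Lyz2 out of the macrophage list were added after seeing the data. Figures were drawn with matplotlib 3.10.9.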

Results

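RNA sequencing was carried out on abdominal aorta taken from mice at day 7 after induction of an aneurysm, a local widening of the artery wall. The samples came from Olfr2 knockout (KO) and wild type (WT) mice, with 3 libraries for each genotype. Olfr2 encodes an olfactory receptor, a G protein-coupled receptor of the family first described in the nose. The libraries held 17248918, 18791519 and 21872027 gene counts in KO replicates 1 to 3 and 17987404, 17388340 and 17551736 in WT replicates 1 to 3. Pairwise Pearson correlations of log2 CPM (counts scaled to library size) lay between 0.9676 and 0.9817, and no 2 libraries agreed within sampling noise. The labels do not say how many animals gave each library, so p-values measure the spread between these libraries. All 6 libraries held reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and at most 3 reads of Xist, the RNA that silences an X chromosome in females. The list of sex-linked genes had 4 members tested, of which 0 passed adjusted over the list alone.

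The targeted gene was examined first. Olfr2 (ENSMUSG00000070417, chromosome 7, 106995399 to 107006072, minus strand, GRCm38, protein-coding) had 0 counts in all 6 libraries, KO and WT alike. A count of 0 allows up to 3 counts, which is 0.174, 0.16 and 0.137 CPM in KO replicates 1 to 3 and 0.167, 0.173 and 0.171 CPM in WT replicates 1 to 3. Olfr2 was therefore not detectable at this depth in either genotype, and its count does not check the genotype labels. Of 1407 genes named Olfr in the table, 130 had any count. Such limits cover counting error alone.

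The comparison of KO with WT asks which transcripts of the aneurysm tissue differ where Olfr2 is missing. Of 16237 tested genes 2 passed, both higher in KO. Ighg3, the constant region of an immunoglobulin G heavy chain (ENSMUSG00000076615, chromosome 12, 113356224 to 113361232), stood at 21.6 ± 9.69 CPM in KO and 0.805 ± 0.527 CPM in WT (SD, n = 3 each). Its log2 fold change was 4.72 (SE 0.46, adjusted p = 0.0394, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Myom1, which encodes the sarcomere protein myomesin (ENSMUSG00000024049, chromosome 17, 71002633 to 71126856), stood at 57.2 ± 12.2 CPM in KO and 19.1 ± 1.44 CPM in WT (SD, n = 3 each). Its log2 fold change was 1.58 (SE 0.16, adjusted p = 0.0394, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Ighg3 has close relatives among the immunoglobulin constant regions that can share reads, so its level is uncertain. Without WT replicate 3 the test called 155 genes, without KO replicate 1 or without WT replicate 1 it called 0, and DESeq2 called 451 with all 6 libraries. Without KO replicate 3 the calls were Ighg2b and Ighg3, while Myom1 stood at a log2 fold change of 1.62 with an adjusted p of 0.0647. At an unadjusted p under 0.05 there were 1836 genes, 849 higher and 987 lower in KO. Other splits of the 6 libraries into 3 and 3, which mix the genotypes, gave 391 to 1109 such genes. The KO and WT libraries did not overlap for 16.8% of tested genes, where chance gives 10%. Principal component 1 held 31.4% of the variance and placed the KO libraries at -32.1, -18.5 and -20.1 and the WT libraries at 30.2, 37.7 and 2.9.

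Transcripts of the contractile apparatus of smooth muscle were higher in KO. Of 22 tested members of that list, 21 had a higher mean in KO and 15 passed, adjusted over the list alone, all of them higher, while 0 passed over all genes tested. Myh11, the smooth muscle myosin heavy chain, stood at 251 ± 56.7 CPM in KO against 94.2 ± 12.5 CPM in WT (SD, n = 3 each), a log2 fold change of 1.42 (SE 0.18). Calponin, encoded by Cnn1, stood at 110 ± 24.5 against 41.2 ± 13.5 CPM, and the integrin subunit gene Itga8 at 145 ± 34.9 against 39.1 ± 20.01 CPM (SD, n = 3 each). The thin filament gene Lmod1 had a log2 fold change of 1.01 (SE 0.17) and Acta2, smooth muscle alpha-actin, of 0.78 (SE 0.24). Each of these 5 genes passed adjusted over the list alone, with an adjusted p over all genes of 0.101 for Myh11, 0.102 for Cnn1, Itga8 and Lmod1, and 0.261 for Acta2 (edgeR's quasi-likelihood test, Benjamini-Hochberg). Tagln had a log2 fold change of 0.57 (SE 0.30) and did not pass, and 67.9% of its exon bases overlap Pcsk7 and Gm48529, so its count is uncertain. The mean log2 CPM of the list was 0.85 higher in KO, and camera, limma's competitive gene set test, gave an adjusted p of 1.35e-14 with its preset correlation. The adjusted p = 0.504 with an estimated correlation (limma). All 3 KO libraries lay above all 3 WT libraries (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). With the white adipocyte score as a covariate the contractile difference was 0.75 (SE 0.27 over libraries, against 0.16 without it) and 6 members passed.

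**Figure D1:**
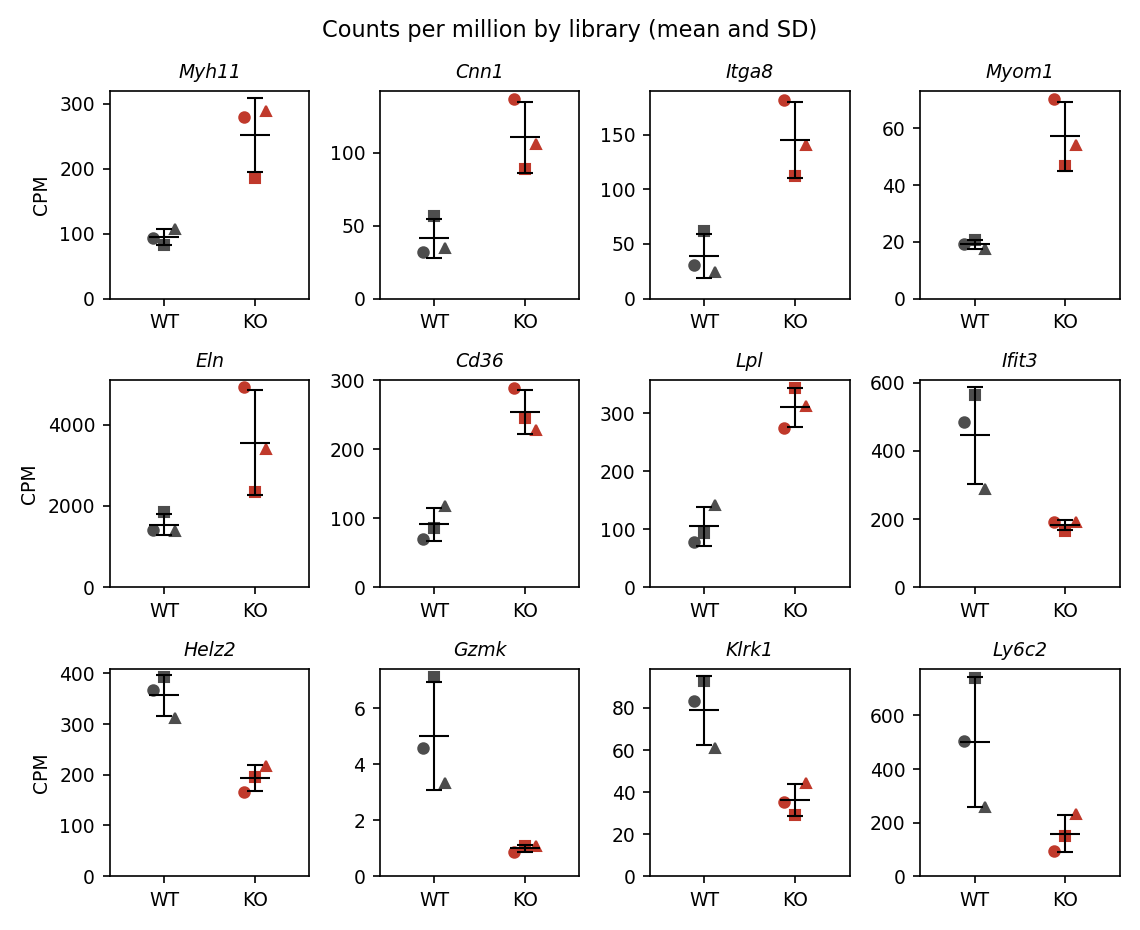
CPM (vertical axes, linear, from 0) of 12 genes in the 3 WT and 3 KO libraries, one point per library, with black lines for the mean and SD. The genes were chosen after their values were seen. In each of the 12 panels the KO and WT points do not overlap, for example Myom1 at 57.2 against 19.1 CPM on average.

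By rank, 10 genes per direction were named, of which Myom1 passed and the other 19 did not. Beside Myh11 and Cnn1, those with higher values in KO were the fatty acid transporter gene Cd36 (log2 fold change 1.48, SE 0.19), lipoprotein lipase Lpl (1.56, SE 0.21), Scube3 (1.30), Mrvi1 (1.02), the actin regulator Enah (0.79), the thyroid hormone receptor Thrb (1.38) and Npnt (1.36). Those with lower values were Klrb1c (-1.21), Slc4a11 (-1.14), Adgrg5 (-0.86), the granzyme gene Gzmk (-2.31), Dnase1l3 (-1.13), Trim14 (-1.07), Hsh2d (-1.33), Helz2 (-0.89), the costimulatory receptor Cd40 (-0.68) and Uba7 (-0.69). The adjusted p-values of these 19 were 0.101 or 0.102 (edgeR's quasi-likelihood test, Benjamini-Hochberg). They were taken by smallest unadjusted p, and in each the KO and WT libraries did not overlap. The rule did not require that of them, but so small a p favours it, so it adds no support. Of the exon bases of Trim14, 38% overlap another gene, so its count is uncertain.

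Interferon-stimulated genes, T cell genes and natural killer (NK) cell genes were lower in KO. Of 20 tested interferon response genes, 20 had a lower mean in KO and 19 passed, adjusted over the list alone, with 0 over all genes tested. Ifit3, an antiviral effector, stood at 183 ± 14.5 CPM in KO and 446 ± 142 CPM in WT (SD, n = 3 each), a log2 fold change of -1.28 (SE 0.22). Ifit2 (-1.19), Ifit1 (-0.99) and Mx2 (-0.86) passed in the same way. Ifit genes have similar copies that can share reads, so single values are uncertain. The list's mean log2 CPM differed by -0.92, with an adjusted p of 4.48e-17 by camera (limma) at the preset correlation. With an estimated correlation the adjusted p = 0.566. With the white adipocyte score as a covariate 0 of its members passed and the difference was -0.44 (SE 0.20 over libraries, against 0.24 without it).

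T cell genes showed the same direction. All 19 tested members had a lower mean in KO and 17 passed, adjusted over the list alone. Trbc2 and Trac, constant regions of the T cell receptor, had log2 fold changes of -0.72 (SE 0.12) and -0.75 (SE 0.14). Cd3e, a chain of the receptor complex, stood at 11.01 ± 1.72 against 15.8 ± 1.11 CPM (SD, n = 3 each). The list mean differed by -0.69, with an adjusted p of 4.64e-16 by camera (limma). The adjusted p = 0.417 with an estimated correlation. With the covariate the difference was -0.68 (SE 0.15 over libraries, against 0.09 without it) and 6 members passed. Of 12 tested natural killer cell genes, 9 passed, all lower, adjusted over the list alone. The activating receptor gene Klrk1 had a log2 fold change of -1.12 (SE 0.19), Klrb1c of -1.21 (SE 0.15) and granzyme Gzmb of -1.36 (SE 0.24). The list mean differed by -0.91, with an adjusted p of 6.75e-09 by camera. With an estimated correlation the adjusted p = 0.566. Without KO replicate 1 and without WT replicate 2 the members passing numbered 3, and without KO replicate 2 they numbered 4. With the covariate 1 member passed and the difference was -0.43 (SE 0.45 over libraries, against 0.34 without it).

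The dendritic cell and MHC class II lists had lower means in KO. All 13 tested dendritic cell genes had a lower mean and 3 passed, adjusted over the list alone, Ccr7 (-1.14), Fscn1 (-0.92) and Flt3 (-0.75). Camera (limma) gave an adjusted p of 1.86e-05 at a mean difference of -0.54, and with an estimated correlation the adjusted p = 0.566. Of 10 MHC class II genes 10 had a lower mean and 6 passed. H2-Ab1, a chain of the antigen-presenting molecule, stood at 1712 ± 222 against 2581 ± 499.9 CPM (SD, n = 3 each), and H2-DMb1 had a log2 fold change of -0.45. Camera (limma) gave an adjusted p of 1.91e-06 at a mean difference of -0.49, and with an estimated correlation the adjusted p = 0.566. Without KO replicate 3, without WT replicate 2 or without WT replicate 3 the class II members passing numbered 0, and without KO replicate 2 they numbered 1. The dendritic cell members passing numbered 7 without KO replicate 1 and 5 without WT replicate 1.

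Among 12 classical monocyte genes, 5 passed as lower and 1, Chil3 (0.53), as higher, adjusted over the list alone. Ly6c2, a surface marker of inflammatory monocytes, stood at 159 ± 67.9 against 501 ± 241 CPM (SD, n = 3 each), a log2 fold change of -1.65 (SE 0.40), though Ly6c genes share sequence and its count is uncertain. Gpr141 (-0.79), Ifitm6 (-1.11) and Plac8 (-0.86) also passed as lower. The list mean differed by -0.43, with an adjusted p of 0.00785 by camera (limma), and with an estimated correlation the adjusted p = 0.566. With the covariate 0 members passed and the difference was -0.17. Macrophage markers had a list mean difference of -0.07 with an adjusted p of 0.024, which with an estimated correlation was adjusted p = 0.766, and 0 of 20 members passed. Lyz2, near 0 in WT replicate 2, pulls that mean up, and without it the difference was -0.21 (SE 0.04 across 19 genes). Cd68 (-0.29, SE 0.22), Adgre1 (-0.13, SE 0.22) and Laptm5 (-0.56, SE 0.17) were among them. The list of lipid-laden macrophage genes was higher by 0.46, with an adjusted p of 0.00128, and with an estimated correlation the adjusted p = 0.648. Its 3 passing members of 17 were Cd36, Lpl and Atp6v0d2 (1.56, SE 0.31), of which Cd36 and Lpl are also expressed by fat cells. Without KO replicate 1 there were 6 and without WT replicate 2 there were 5. Trem2 had a log2 fold change of 0.17 (SE 0.20) and Abcg1 of -0.46 (SE 0.16).

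**Figure D2:**
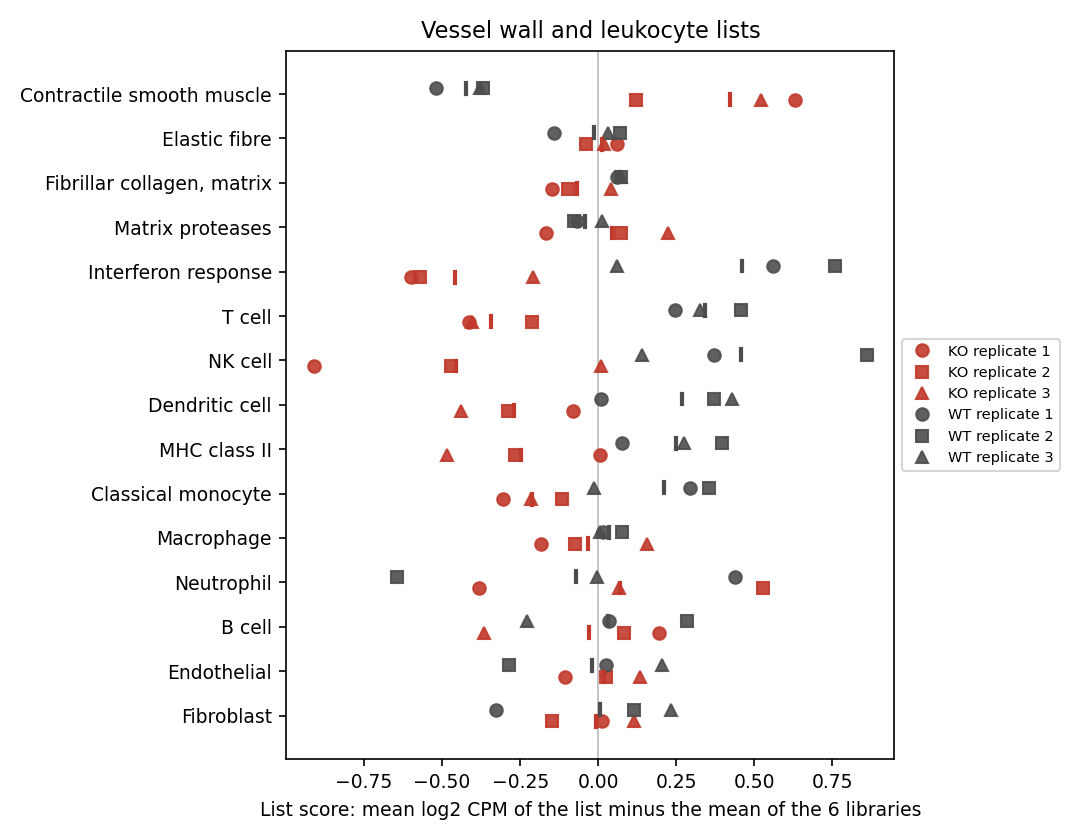
Mean log2 CPM of 15 lists in each library, less the mean of the 6 libraries (horizontal axis, log2 units), with KO in red, WT in grey and short lines for group means. The contractile list lies higher in all KO libraries, and the interferon, T cell and NK cell lists lie lower in all KO libraries.

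Inflammation genes of the fixed panel did not pass. Il1b stood at 251 ± 105 against 247 ± 38.9 CPM (SD, n = 3 each), a log2 fold change of 0.03 (SE 0.27). Il6 (0.40, SE 0.50), Tnf (-0.32, SE 0.24), Nlrp3 (-0.19, SE 0.16) and Ccl2 (-0.08, SE 0.30) did not pass either. The inflammasome list had an adjusted p of 0.0117 (camera, limma) and a mean difference of -0.19, with 0 of 15 members passing, led by Il18 (-0.79) and Gsdmd (-0.32). With an estimated correlation its adjusted p = 0.576. The list of leukocyte adhesion genes differed by -0.24, with an adjusted p of 0.00334, and with an estimated correlation the adjusted p = 0.602. Of its 13 tested members 3 passed adjusted over the list alone, among them Itgb7 (-0.58) and Selplg (-0.48), and without KO replicate 1, KO replicate 2 or WT replicate 2 there was 1. The cell death list differed by -0.16 with an adjusted p of 0.00458, and with an estimated correlation the adjusted p = 0.566. The member passing was Mlkl (-0.53), which executes necroptosis. Cytokines had an adjusted p of 0.238 and chemokines of 0.115, where Cxcl10 stood at 196 ± 27.8 against 354 ± 113 CPM (SD, n = 3 each) and Ccl22 had a log2 fold change of -0.83.

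Elastin stood at 3553 ± 1296 CPM in KO and 1543 ± 260 CPM in WT (SD, n = 3 each), a log2 fold change of 1.20 (SE 0.27, adjusted p = 0.142 by edgeR's quasi-likelihood test). Eln and Ltbp1 (0.89, SE 0.18) passed adjusted over the list alone among 19 elastic fibre genes, and 0 over all genes tested. The list as a whole had an adjusted p of 0.543, a mean log2 fold change of 0.02, a median of -0.10 and a camera direction down, so its signs differ. Without WT replicate 1 or without WT replicate 3 the members passing numbered 0. Fibrillar collagen genes had a mean difference of -0.13 and an adjusted p of 0.0263 (camera, limma), and with an estimated correlation the adjusted p = 0.6. Of its 27 members 0 passed, among them Col1a1 (-0.55, SE 0.26) and Col3a1 (-0.18, SE 0.20) with the cross-linking enzyme gene Lox at -0.08 (SE 0.14). Of 24 matrix protease genes, 2 passed adjusted over the list alone, Mmp25 lower (-1.03, SE 0.19) and Adamts8 higher (1.47, SE 0.30), and the list had an adjusted p of 0.982. Mmp2 (-0.38, SE 0.13), Mmp3 (-0.11, SE 0.25), Mmp9 (0.33, SE 0.25) and Mmp12 (1.04, SE 0.36) did not pass. Protease inhibitors had an adjusted p of 0.448, with Serpine2 (0.76) and A2m (-2.14) passing adjusted over the list alone, and Timp1 at 0.08 (SE 0.20).

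White adipocyte genes were higher in the KO libraries and in WT replicate 3. Of 15 tested, 15 had a higher mean in KO and 3 passed adjusted over the list alone, Acvr1c (2.42), Fabp4 (1.61) and Pparg (0.74). Adiponectin, Adipoq, stood at 135 ± 50.8 against 46.1 ± 43.6 CPM (SD, n = 3 each). The list mean differed by 1.61 with an adjusted p of 3.3e-08 (camera, limma), and with an estimated correlation the adjusted p = 0.6. The KO and WT scores overlapped. Without WT replicate 3 there were 15 members passing, and 0 without KO replicate 1, without KO replicate 2, without WT replicate 1 or without WT replicate 2. Brown adipocyte genes differed by 1.73, with an adjusted p of 0.000198, and with an estimated correlation the adjusted p = 0.566. Its passing members of 8 were Cox8b (2.95) and Cox7a1 (1.65). Fatty acid oxidation genes differed by 0.29 and had an adjusted p of 0.000155, and with an estimated correlation the adjusted p = 0.614, with Acadm at 0.64 and 0 of 16 passing. Oxidative phosphorylation genes differed by 0.16 and had an adjusted p of 0.00146, and with an estimated correlation the adjusted p = 0.647, with Ndufb3 at 0.41 and 0 of 28 passing.

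Transcripts of the mitochondrial genome made up 5.32, 2.59 and 2.32% of counts in KO replicates 1 to 3 and 1.84, 1.88 and 1.56% in WT replicates 1 to 3. Of 12 such genes tested, 11 passed adjusted over the list alone, all higher in KO, such as mt-Nd2 (1.33) and mt-Cytb (1.04). The list mean differed by 0.85 with an adjusted p of 5.01e-07 (camera, limma), and with an estimated correlation the adjusted p = 0.602. Without KO replicate 1 the members passing numbered 3, without WT replicate 1 they numbered 7, and without WT replicate 2 or without WT replicate 3 they numbered 0. Skeletal muscle genes were high in KO replicate 3 alone. Of 9 tested 8 passed adjusted over the list alone, among them Acta1 (6.05, SE 2.11) and Casq1 (3.45, SE 1.03), and the list adjusted p was 0.0315. With an estimated correlation the adjusted p = 0.766, and without KO replicate 3 the list difference was -0.28. Without KO replicate 3 or without any of the WT libraries 0 of its members passed. The heat shock list differed by 0.84 with an adjusted p of 0.000974, and with an estimated correlation the adjusted p = 0.766, with 0 of 13 passing, and without KO replicate 3 the difference was 0.15.

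**Figure D3:**
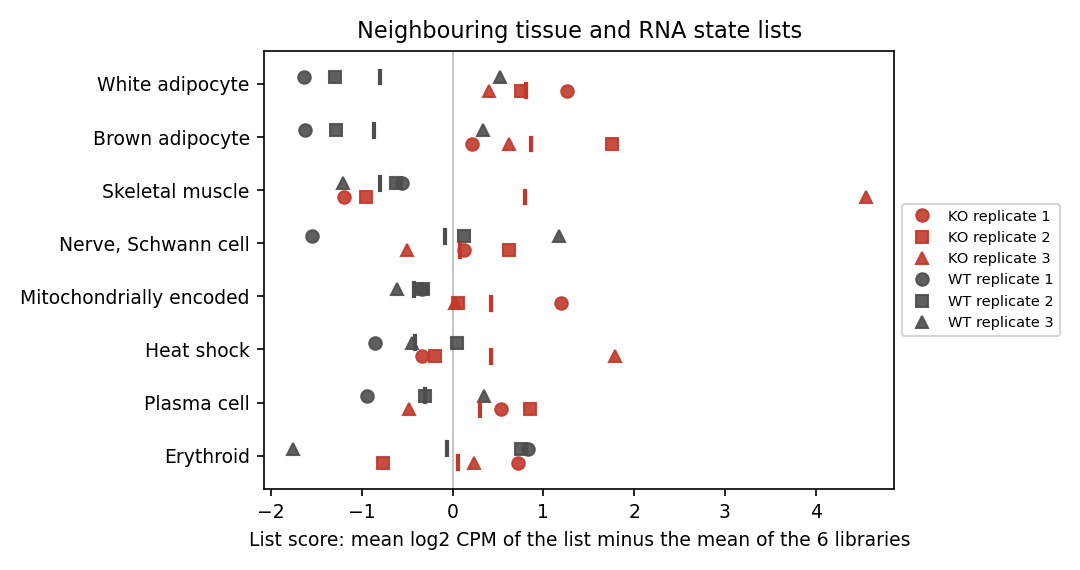
Mean log2 CPM of 8 lists for neighbouring tissues and RNA state in each library, less the mean of the 6 libraries (horizontal axis, log2 units), with KO in red, WT in grey and short lines for group means. KO replicate 3 stands apart for skeletal muscle and heat shock genes, and WT replicate 3 lies among the KO libraries for white adipocyte genes.

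The other lists were not called by camera (limma, adjusted p with the preset correlation). Vessel wall and stromal lists were fibroblast markers at adjusted p = 0.854, activated fibroblasts at 0.547, endothelial markers at 0.821, lymphatic endothelium at 0.452, lymph node stroma at 0.271 and mesothelium at 0.481. Ccl21a (2.51) passed in the 2 lymphatic lists alone, and has near-identical copies, so its count is uncertain. Blood and immune lists were neutrophil genes at adjusted p = 0.262, with S100a8 at 0.28 (SE 0.11), B cell genes at 0.854, plasma cell genes at 0.497, with Ighg3 (4.72) and Ighg2b (3.83) passing in the list alone and Ighg3 over all genes as well, mast cell genes at 0.508, with Kit (-0.56) passing in the list alone, resident macrophage genes at 0.42, platelet genes at 0.481 and erythroid genes at 0.955. Nerve and Schwann cell genes had an adjusted p of 0.73 and ganglion neurons of 0.964. Pathway lists were olfactory receptor signalling at adjusted p = 0.251, with Rtp4 (-0.91) passing in the list alone, TGF-beta signalling at 0.575, with Ltbp1 (0.89) passing in the list alone, osteochondrogenic genes at 0.854, cell cycle at 0.42, with Mki67 at 0.20 (SE 0.18), glycolysis and hypoxia at 0.749, oxidative stress at 0.481, unfolded protein response at 0.251, cholesterol biosynthesis at 0.0534, immediate early genes at 0.598 and ribosomal proteins at 0.481. The remaining 6 lists had under 5 members tested. Of these, cardiac muscle had Ryr2 (1.79) and Ttn (4.99, and -0.04 without KO replicate 3) passing in the list alone, and pancreas had Cpb1 (1.25), while adrenal, kidney, liver and sex-linked genes had 0.

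A knockout line can carry flanking sequence of another strain, so calls were counted by position. Within 10 Mb of Olfr2, 0 of 192 tested genes were called, against 2 of 16045 elsewhere (Fisher's exact p = 1, two-sided). With only 2 calls in all, a count of 0 there was almost certain in advance, so this test cannot decide on flanking sequence. Mrvi1, which did not pass, lies on chromosome 7 at 110868266 to 110982461, within that window.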

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

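Of the alternatives, leaving out KO replicate 3 with WT replicate 2, the white adipocyte covariate, leaving out mitochondrially encoded genes, and counting members passing with libraries left out were chosen after seeing the data. Where a call was lost or gained, the cause was not tested. Against 2 genes called, 644 were called with no filter beyond 1 count (342 higher, 302 lower), 451 by DESeq2 (168 higher, 283 lower), 0 by limma-voom, 0 by limma-voom with sample quality weights, 1 by the robust quasi-likelihood fit (Myom1), 0 with protein-coding genes only, and 0 with the white adipocyte covariate. With all libraries and the first settings, edgeR had 1836 genes at an unadjusted p under 0.05. Leaving out one library gave 0 to 155 genes, the 155 without WT replicate 3, and without WT replicate 2 the call was Hspb7. Without KO replicate 3 and WT replicate 2 the count was 3, sharing 0 with the 2. Gene lists called numbered 20, against 0 with an estimated correlation, 0 by fry, and 15 to 23 with libraries left out. With the white adipocyte covariate 16 were called, of which 10 are among the 20. Near Olfr2, 0 to 4 genes were called with a library left out, the 4 (Trim30d, Thrsp, Trim34a, Dgat2) without WT replicate 3 (Fisher's exact p = 0.111). DESeq2 size factors, upper quartile factors and library size alone called the same 2 genes. The Olfr2 count of 0 is a raw count that no scaling, filter or left-out library can change, so the alternatives do not test it.

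The labels give KO and WT the same replicate numbers and state no pairing. Deviations of same-numbered libraries correlated at -0.101, -0.062 and -0.12, so no shared deviation was seen. A pairing that left no trace in these counts cannot be excluded. With the replicate block 0 genes and 22 lists were called, and Il1b was at -0.05.

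Signs changed for the following values. Il1b was at -0.05 by limma-voom, and Ccl2 at 0.17 with quality weights. With the covariate Tnf was at 0.02, Ccl2 0.63, Cd68 0.11, Adgre1 0.32, Pecam1 -0.02, Lyz1 0.19 and the white adipocyte list at 0 by construction. With libraries left out, KO replicate 3 with WT replicate 2 included, log2 values ranged from -0.13 to 0.07 for Lox, -0.36 to 0.14 for Mmp3, -0.07 to 0.5 for Mmp9, -0.17 to 0.33 for Timp1, -0.34 to 0.28 for Il1b, -0.25 to 0.83 for Il6, -0.48 to 0.04 for Tnf, -0.33 to 0.31 for Ccl2, -0.45 to 0.01 for Cd68, -0.36 to 0.05 for Adgre1, -0.1 to 0.44 for Cd79a, -0.16 to 0.16 for Pecam1, -1.58 to 6.91 for Acta1, -3.05 to 0.73 for Lyz1, -2.51 to 0.22 for Ighm, -2.41 to 0.41 for Igkc, -2.09 to 0.05 for Jchain, -0.32 to 4.1 for Hspa1a, -0.38 to 5.88 for Ttn and -0.28 to 2.83 for the skeletal muscle list.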

Other observations

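The choice of both tests of a lower leukocyte share, and of those for fat or muscle in the T cell, NK cell and interferon lists, for fewer macrophages, for Lyz1 reads and for members passing in 4 lists was made after the result was seen, as were the covariate, the margin of 1 SE in tests with it, leaving Lyz2 out of the macrophage list and the removal of KO replicate 3 with WT replicate 2. Immunoglobulin transcripts did not move together. Ighg2b stood at 43.8, 58.3 and 7.37 CPM in KO replicates 1 to 3 and 1.69, 4.18 and 1.84 CPM in WT replicates 1 to 3, and Ighg1 at 25.5, 26.4 and 0.0466 against 0.272, 2.12 and 0.748 CPM. Ighm, the IgM heavy chain, was highest in WT replicate 3 at 2060 CPM, against 153 to 251 in the other 5 libraries, and Igkc and Jchain were also highest there, at 989 and 147 CPM. Without WT replicate 3 the log2 fold changes of Ighm, Igkc and Jchain were 0.22, 0.41 and 0.05. These genes share sequence, so single values are uncertain.

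Other values stood apart in single libraries. Hspa1a, an inducible chaperone gene, stood at 306 CPM in KO replicate 3 and between 4.02 and 17.3 CPM in the others, and Acta1 at 193 CPM there. Cidea, a lipid droplet gene, stood at 27.5 CPM in KO replicate 2 and at most 3.27 CPM elsewhere. Olfr1033, the most abundant Olfr-named gene examined, stood at 126 ± 7.19 CPM in KO and 88.4 ± 42.9 CPM in WT (SD, n = 3 each), with a log2 fold change of 0.51 (SE 0.29). Lpl and Cd36 were at 275 and 290 CPM in KO replicate 1, 343 and 245 in KO replicate 2 and 312 and 229 in KO replicate 3, where Adipoq stood at 191, 91.5 and 123 CPM. They were at 78.8 and 70.4 CPM in WT replicate 1, 94.2 and 85.5 in WT replicate 2 and 142 and 118 in WT replicate 3, where Adipoq stood at 20.2, 21.6 and 96.4 CPM. With the white adipocyte covariate the log2 fold changes of Lpl and Cd36 were 1.13 and 0.98, against 1.56 and 1.48 without it. White adipocyte scores fall into separate clusters, with WT replicates 1 and 2 apart from the rest, so no correlation over the 6 libraries is given. Principal component 1 also placed WT replicates 1 and 2 farthest from the KO libraries, at 30.2 and 37.7, against 2.9 for WT replicate 3. In the file headers WT replicates 1 and 2 carry consecutive numbers, and the other libraries do not. What the numbers stand for is not given, so anything they mark in WT replicates 1 and 2 cannot be told apart from genotype there.

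Contractile genes were higher in KO. Against TMM scaling as the cause, the list stayed called with library size alone, at a difference of 0.88, and with DESeq2 size factors, at 0.84. A lower leukocyte share would raise every other cell type alike, yet the contractile list exceeded the endothelial list by 0.81 and the fibroblast list by 0.86 (SE 0.12 across genes). Such an SE takes genes as independent and can understate the spread between libraries. The estimated correlation between genes was 0.22 in the contractile, 0.47 in the endothelial and 0.24 in the fibroblast list. Whether more perivascular fat in the KO samples was the whole cause cannot be decided. With the white adipocyte score as covariate the difference was 0.75 (SE 0.27), against 0.85 (SE 0.16) without it. That score was 6.64, 6.13 and 5.78 in KO replicates 1 to 3 and 3.74, 4.08 and 5.9 in WT replicates 1 to 3. The fit thus separates fat from genotype mainly through WT replicate 3. The difference of 0.75 exceeds a bound of 0.4 by more than 1 SE but less than 2. That bound was written before the result of this fit, but the covariate was chosen after seeing the data. Members passing went from 15 to 6 as the SE grew. Fat as part or all of the cause stays open, as does genotype itself. The mitochondrial share of counts was also higher in KO (5.32, 2.59 and 2.32% in replicates 1 to 3) than in WT (1.84, 1.88 and 1.56%). Whether the contractile difference goes with that share was not tested.

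T cell, NK cell and interferon genes were lower in KO, and fewer cells were not tested against a weaker response per cell. An equal fall of all leukocytes as the whole cause is argued against. The T cell list fell by more than the macrophage list, with a difference of -0.62 (SE 0.15 across genes). With Lyz2 left out of the macrophage list that difference was -0.48 (SE 0.06). Against the B cell list the difference was -0.63 (SE 0.14 across genes). A lower leukocyte share that differs between cell types stays open. SEs across genes take genes as independent and can understate the spread between libraries. The estimated correlation between genes was 0.15 in the T cell, 0.43 in the macrophage, 0.26 in the B cell, 0.69 in the NK cell and 0.65 in the interferon list. Dilution by fat or muscle in the KO samples would lower every other cell type alike only if the added tissue brought none of those cells. That was not tested, so the following gaps cannot decide on dilution. Each of the T cell, NK cell and interferon lists fell by more than the fibroblast, endothelial, macrophage and B cell lists. The smallest gaps with all members were -0.86 (SE 0.16 across genes) for interferon, -0.85 (SE 0.17) for NK cell and -0.62 (SE 0.15) for T cell genes. Lyz2 pulls the macrophage mean up, and with it left out the gaps to that list were -0.71 (SE 0.07), -0.70 (SE 0.09) and -0.48 (SE 0.06). Without KO replicate 3, the library with muscle transcripts, the interferon difference was -1.05. A trend with fat content across libraries cannot be excluded for the T cell list. The T cell difference was -0.68 (SE 0.15 over libraries) with the adipocyte covariate and -0.69 (SE 0.09) without it. That rests mainly on WT replicate 3, the only WT library with an adipocyte score among the KO ones. Its T cell score was 4.5, against 3.76, 3.96 and 3.77 in KO replicates 1 to 3. For the NK cell list such a trend cannot be told apart from genotype, since the difference was -0.43 with an SE of 0.45. Nor can it for the interferon list, which stayed called by camera (limma, adjusted p = 7.93e-07 at the preset correlation) but had a difference of -0.44 (SE 0.20) with the covariate against -0.92 (SE 0.24) without it. Genotype itself stays open.

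Lyz2, the lysozyme of macrophages and neutrophils, stood at 31.7 CPM (523 counts) in WT replicate 2 and between 3870 and 5900 CPM in the other 5 libraries, while Lyz1 stood at 448 CPM there and at most 39.3 elsewhere. Fewer macrophages in that library are argued against, since the median of the other macrophage markers lay 0.50 above the other WT libraries on the log2 scale. Reads assigned to Lyz1 in place of Lyz2 would keep the sum, but Lyz1 and Lyz2 together reached 11.2% of the mean of the other WT libraries. A different strain segment around Lyz2 in that library could not be decided, with 1 of 47 genes within 5 Mb standing apart against 0.82% elsewhere (one-sided Fisher's exact p = 0.321). An allele changed at Lyz2 alone could leave its neighbours as they are, so this count could not test it and it stays open. No biological explanation beyond these was tested, since the labels give no group that sets this library apart.

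Only 10 splits of the 6 libraries into 3 and 3 exist, so no share under 0.05 can be reached by any of these counts. For genes called, 1 split gave as many, the real one with 2, and the highest other gave 0. For DESeq2, 1 split gave as many, the real one with 451, and the highest other gave 51. For gene lists, 5 splits called as many, with 20 in the real split and 24 in the highest other. For members passing adjusted over the list alone, the real split gave 15 contractile members against 2 in the highest other, 17 T cell members against 0, 19 interferon members against 13 and 9 NK cell members against 5, and in each of these 4 lists 1 split gave as many. Those 4 lists were picked after their member counts were seen. Over all 56 lists, 25 had a member passing in the real split, and for 16 of these no other split passed as many. A further 20 lists had members passing in another split and 0 in the real one, among them heat shock with 9.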
